A study of Mus musculus with 47 samples.

How the data were processed

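RNA was measured by stranded sequencing in the cerebral cortex of 47 mice aged 6 months, 23 female and 24 male. The genotypes were wild type (WT), Ccdc82+/-, Ccdc82-/-, Q140, and Q140 crossed with Ccdc82+/- or Ccdc82-/-. Q140 is a knock-in model of Huntington's disease with an expanded CAG repeat in Htt, and the titles give the mice that carry it as heterozygous. Every group held 4 females and 4 males except Q140 with Ccdc82-/-, which held 3 females and 4 males. Each library was treated as 1 mouse, as the titles number them within genotype and sex.

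The deposited count table holds raw read counts per gene, with no normalization. The deposited FPKM table holds FPKM values, scaled to gene length and library total. Over 19539 genes, the ratio of FPKM to counts, after division by the library total, varied between libraries by at most 1.01e-14 relative to its size, so each gene had the same length in all libraries. The submitters' processing notes name STAR 2.7.5c, SAMtools 1.10, HTSeq 0.12.3 and the builds GRCm38 and mm10; the annotation release was not given in the sources used here. Coordinates came from GENCODE M21 on GRCm38, in which 48435 of the 48795 gene identifiers were found, all on the same chromosome as the deposited files give and 48421 on the same strand.

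Library totals ranged from 43554594 to 61370843 counts, with a median of 50473683. Counting error was small beside the differences between mice: the chi-square per gene between replicates of a group was at least 3.87 and at most 23.8, so no library was a duplicate of another of its group; pairs across groups were not compared. Xist and Y-linked genes were checked as sex-linked label check genes and matched the labelled sex in 47 of 47 libraries.

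Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 19174 genes. Counts were normalized by TMM and fitted in edgeR 4.0.16 with the quasi-likelihood method (robust), with the 6 genotype means and sex as terms and all 47 libraries in 1 fit. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called changed, with no fold threshold. The contrasts were each Ccdc82 genotype against its control with and without Q140, Q140 against its control on each Ccdc82 genotype, the interactions, and 3 pooled effects: Q140 averaged over the 3 Ccdc82 genotypes, and Ccdc82+/- and Ccdc82-/- each averaged over mice with and without Q140. Differences of the pooled effects between the sexes were tested in a fit with genotype-by-sex means. Standard errors are those implied by the F statistic.

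Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and, beside it, an estimated correlation, and adjusted over the 29 lists of a contrast. The lists covered HD onset modifier and mismatch repair genes, medium spiny neuron identity genes, clustered protocadherins, markers of upper and deep layer excitatory neurons, interneurons, astrocytes, reactive astrocytes, microglia, oligodendrocytes and myelin, oligodendrocyte precursors, endothelial cells and pericytes, red blood cells, choroid plexus, meningeal fibroblasts, thalamus and hippocampus, and genes of cholesterol synthesis, glutamate and GABA receptors, neuronal activity, p53 and DNA damage, interferon, heat shock, the unfolded protein and integrated stress response, nuclear and mitochondrially encoded respiration, ribosomal proteins, the circadian clock and polycomb-repressed developmental regulators. The mean of each list per mouse, relative to WT, was also compared by permutation of the Q140 labels within Ccdc82 genotype and sex (99999 permutations) or by exact permutation tests between groups.

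A Q140 signature score summarised each mouse. The score was the mean, over signature genes, of log2 CPM (prior count 2) relative to WT, signed by the direction of the Q140 effect. Signature genes were those called in a fit of WT and Q140 mice, or the 50 with the smallest p where fewer than 50 were called. In each of 8 folds the WT and the Q140 mouse with the same number were left out, so that no mouse was scored by genes it had helped to choose. The WT reference of a fold was the mean of its remaining WT mice, and mice of other genotypes took the mean over the folds. Scores were compared by two-sided exact permutation tests, with 95% intervals by inversion of the exact test, and interactions by 100000 permutations. These permutations moved finished scores and did not choose the genes anew. The folds shared mice, so WT and Q140 scores were not independent, and their p-values are approximate. WT and Q140 mice had the score of a single fold and other mice a mean over folds, so these scores differ in kind. The kept WT mice set the reference and helped to choose the genes, so other mice without Q140 need not average at it.

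The genotype groups, the tests, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where a choice is stated to have been made later. The rule named, per contrast, up to 12 risen and 12 fallen genes with the smallest p among called genes with a regular symbol and a mean of at least 1 CPM, up to 4 members of each list called by camera, and Ccdc82 and Htt. The contrasts of Q140 on a Ccdc82 mutant background were not in that rule. Called genes within 5 Mb of either locus were reported apart. The alternatives were median-of-ratios size factors, DESeq2 1.42.0, no filter, a filter of at least 1 CPM in at least 7 libraries, no sex term, the replicate block, the plate column as a factor, 2 surrogate variables from sva 3.50.0, limma-trend on log2 FPKM with a pseudocount of 0.5, and fits of the compared groups alone. Analyses ran in R 4.3.3.

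The fits were tested on simulated data with 50 genes at each of 4 folds, all changed at once. They were drawn among genes with a mean of at least 1 CPM, and counts were simulated independently for each library. In Ccdc82-/- against WT, 38% of genes changed 1.1-fold, 62% of those changed 1.2-fold and 98% of those changed 1.5-fold were recovered among 19174 genes. In the pooled Q140 effect the shares were 70%, 80% and 100%. Where few genes truly change, the adjusted cutoff is stricter, so these shares may be too high for such a comparison. Reads, splice isoforms and the repeat length were not analysed here, and 1 gene that the rule named is not reported here.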

Results

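Gene expression in the cerebral cortex was compared between 47 mice of 6 genotypes at 6 months of age. WT, Ccdc82+/-, Ccdc82-/-, Q140 and Q140 with Ccdc82+/- were represented by 8 mice each, and Q140 with Ccdc82-/- by 7. The total count per library lay between 43554594 and 61370843. Q140 mice, heterozygous for the allele by their titles, carry an expanded CAG repeat knocked into Htt, the Huntington's disease gene, and the crosses addressed whether loss of Ccdc82, a gene named for its coiled-coil domain, changes expression in the cortex with or without that allele.

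Ccdc82 (ENSMUSG00000079084, chromosome 9, 13246955 to 13292520, GRCm38) fell with each lost copy. Its level was 16.2 ± 1.58 CPM (SD, n = 8) in WT, 10.9 ± 0.962 CPM (n = 8) in Ccdc82+/- and 5.32 ± 0.595 CPM (n = 8) in Ccdc82-/-, so that 67.4% and 32.8% of the WT level remained. In mice with the Q140 allele it was 15.6 ± 0.996 CPM (n = 8), 11.4 ± 0.875 CPM (n = 8) with Ccdc82+/- and 5.51 ± 0.426 CPM (n = 7) with Ccdc82-/-. Reads assigned to the gene remained in every Ccdc82-/- library without Q140, at 221 to 317 counts against 720 to 1048 in WT. The deleted part of the gene was not given in the sources used here, so the remaining reads do not show whether protein was made.

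**Figure D1:**
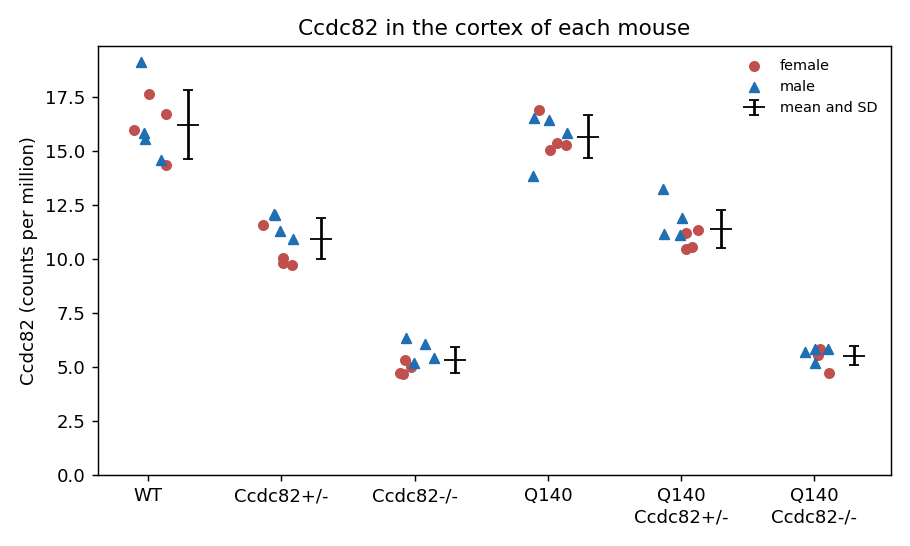
Ccdc82 level in CPM (vertical axis, from 0) in each of the 6 genotypes, with 1 point per mouse and the group mean ± SD. WT averaged 16.2 CPM and Ccdc82-/- 5.32 CPM.

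Loss of Ccdc82 without Q140 gave no other gene that passed the test. In Ccdc82-/- against WT, Ccdc82 fell by 1.61 on the log2 scale (SE 0.058, adjusted p = 3.01e-27), and it was the 1 gene called of 19174 in edgeR. In Ccdc82+/- against WT it fell by 0.57 (SE 0.055, adjusted p = 9.15e-10), again the 1 gene called. At an unadjusted p under 0.05 there were 619 genes in Ccdc82-/- and 690 in Ccdc82+/-, where chance gives 959, and DESeq2 called 1 gene in each. Htt differed by 0.04 (SE 0.025, adjusted p = 0.999) in Ccdc82-/- and by 0.05 (SE 0.025, adjusted p = 0.993) in Ccdc82+/-.

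Among cell type lists, the 20 astrocyte markers had a median log2 change of -0.05 in Ccdc82-/- against WT, with 0 members called over all genes and 0 adjusted over the list alone (camera FDR 0.000223; adjusted p = 0.989 with an estimated correlation). The 85 ribosomal protein genes had a median of -0.03 (FDR 0.000223; adjusted p = 0.989 with an estimated correlation). In Ccdc82+/- the unfolded protein and integrated stress response genes had a median of -0.09 over 27 genes, with 0 called over all genes and 0 adjusted over the list alone (FDR 6.42e-06; adjusted p = 0.323 with an estimated correlation). These comparisons share the WT mice, so their list results are not independent of each other.

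Loss of Ccdc82 in Q140 mice gave the same count. Ccdc82 fell by 1.51 (SE 0.061, adjusted p = 3.48e-25) in Q140 with Ccdc82-/- against Q140, and by 0.46 (SE 0.055, adjusted p = 7.47e-07) in Q140 with Ccdc82+/- against Q140. It was the 1 gene called in each, in edgeR and in DESeq2, with 785 and 1039 genes at an unadjusted p under 0.05. Pooled over mice with and without Q140, Ccdc82 fell by 1.56 (SE 0.042, adjusted p = 3.14e-33) in Ccdc82-/- and by 0.52 (SE 0.039, adjusted p = 1.14e-13) in Ccdc82+/-, and no other gene was called, with 892 and 1019 genes at an unadjusted p under 0.05.

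Meningeal fibroblast markers were lower in Q140 with Ccdc82+/- than in Q140, whose own list mean was the highest of the 6 genotypes (0.320 relative to WT, against -0.0937 in Q140 with Ccdc82+/- and 0.0195 in Ccdc82+/-). All 16 had values below 0, with a median of -0.37, 0 called over all genes and 8 adjusted over the list alone (FDR 1.46e-16; adjusted p = 0.218 with an estimated correlation). Col3a1, a fibrillar collagen, had a log2 difference of -0.65 (SE 0.203, adjusted p = 0.902) and Dcn, the proteoglycan decorin, one of -0.49 (SE 0.161, adjusted p = 0.902). Reactive astrocyte genes (median -0.15; adjusted p = 0.218 with an estimated correlation) and endothelial and pericyte markers (median -0.08; adjusted p = 0.218 with an estimated correlation) lay in the same direction. In Q140 with Ccdc82-/- against Q140, the oligodendrocyte and myelin genes had a median of -0.08 over 22 genes (FDR 0.0122; adjusted p = 0.796 with an estimated correlation), with Mobp, a myelin protein gene, at -0.19 (SE 0.104, adjusted p = 0.997).

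Few genes differed with the Q140 allele in single comparisons. Against WT, Abca8a, a lipid transporter of the ABC family, rose by 0.43 on the log2 scale (SE 0.067, n = 8 and 8, adjusted p = 0.000437), and Chdh, choline dehydrogenase, by 0.52 (SE 0.087, adjusted p = 0.0012). Camk2n1, an inhibitor of CaM kinase II, fell by 0.22 (SE 0.042, adjusted p = 0.0135) and Ddit4l, a regulator of mTOR signalling, by 0.36 (SE 0.072, adjusted p = 0.0432). Near Htt, Mrpl33, a mitochondrial ribosomal protein gene, rose by 0.27 (SE 0.042, adjusted p = 0.000437), and the pseudogene Gm2420, named after its values were seen, rose by 2.87; how the counting treated reads shared with its parent gene is not given in the sources used here, so its level is uncertain. DESeq2 called 24 genes and a fit with 2 surrogate variables 23, against 6 in edgeR. With the plate column as a factor the calls of Ddit4l (adjusted p = 0.257) and Camk2n1 (adjusted p = 0.0747) were lost, and in a fit of the 2 compared groups alone those of Abca8a (adjusted p = 0.0525), Mrpl33 (0.0782) and Ddit4l (0.176). At an unadjusted p under 0.05 there were 1328 genes.

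On the mutant backgrounds 6 genes were called in Q140 with Ccdc82+/- against Ccdc82+/- and 4 in Q140 with Ccdc82-/- against Ccdc82-/-; the genes given here were chosen after their values were seen. In the former, Abca8a rose by 0.36 (SE 0.068, adjusted p = 0.0138), Camkk2, the kinase upstream of CaM kinases I and IV and of AMPK, fell by 0.12 (SE 0.023, adjusted p = 0.0138) and Gpr153, an orphan receptor, by 0.35 (SE 0.066, adjusted p = 0.0138). In the latter, Car2, a carbonic anhydrase, fell by 0.18 (SE 0.035, adjusted p = 0.0258). Mrpl33, Gm2420 and the hydrolase family gene Abhd1, all near Htt, rose in both. On Ccdc82+/- the calls of Abca8a (adjusted p = 0.0664), Camkk2 and Gpr153 (0.0674 each) and Abhd1 (0.233) were lost with the plate column as a factor. In fits of the compared groups alone Camkk2 (adjusted p = 0.139), Gpr153 and Abhd1 (0.272 each) lost theirs on Ccdc82+/-, and Car2 (0.121) on Ccdc82-/-. With the library-name number as a random block, a setting chosen after the result was seen, the call of Abhd1 was lost on both (adjusted p = 0.204 and 0.055). The counts at an unadjusted p under 0.05 were 993 and 800.

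Averaged over the 3 Ccdc82 genotypes, the Q140 effect held 168 genes, 65 higher and 103 lower in the 23 mice with Q140 than in the 24 without. With limma-trend on FPKM the larger part rose instead, 90 higher and 81 lower. The changes were small, with a median size of 0.12 on the log2 scale, and 19 genes rose and 13 fell by more than 1.2-fold. At an unadjusted p under 0.05 there were 1760 genes, DESeq2 called 239 and a fit with 2 surrogate variables 297. All 168 had the same sign on the 3 backgrounds, which is not independent evidence, since the genes were picked on the average.

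Among genes that fell, Camk2n1 fell by 0.18 (SE 0.024, adjusted p = 8.85e-06), in 23 of 23 mice with Q140. Each mouse was set against the mean of mice without Q140 of its Ccdc82 genotype and sex. Such counts of mice, here and for risen genes, add no support, since the genes were picked in the same mice. Camkk2 fell by 0.10 (SE 0.014, adjusted p = 2.68e-06) in 23 of 23, and Camk2a, the alpha subunit of CaM kinase II, by 0.08 (SE 0.014, adjusted p = 0.000378). Cartpt, the precursor of the CART neuropeptides, fell by 0.41 (SE 0.066, adjusted p = 0.000196) in 23 of 23 mice, Plk5, a polo-like kinase, by 0.34 (SE 0.054) and Gpr153 by 0.26 (SE 0.038). Car2 fell by 0.15 (SE 0.020, adjusted p = 2.53e-06), and Lgi4, Ddit4l and the fatty acid desaturase Fads1 fell by 0.14, 0.25 and 0.08.

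Among genes that rose, Abca8a was higher by 0.36 (SE 0.039, adjusted p = 1.75e-08) in 23 of 23 mice and Chdh by 0.39 (SE 0.051, adjusted p = 2.53e-06) in 22 of 23. Enpp6, a choline phosphodiesterase of newly formed oligodendrocytes, rose by 0.43 (SE 0.077, adjusted p = 0.000641) and Anln, anillin, by 0.37 (SE 0.057, adjusted p = 0.000121). Lrp1b, Efnb2, Cpox and Tpx2 rose by 0.11, 0.10, 0.08 and 0.25.

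Of the 20 astrocyte markers, 0 rose and 4 fell over all genes, and 9 fell adjusted over the list alone (camera FDR 2.66e-09; adjusted p = 0.335 with an estimated correlation). Glul, glutamine synthetase, fell by 0.11 (SE 0.016, adjusted p = 2.15e-05), Kcnj10, the inward rectifier potassium channel of astrocytes, by 0.14 (SE 0.024, adjusted p = 0.000641; 0.0582 without the sex term), Aldoc by 0.10 (SE 0.020) and the glutamate transporter Slc1a2 by 0.08 (SE 0.017). The list mean per mouse differed by -0.0483 (permutation p = 0.00519, 0.0753 adjusted over 29 lists). Reactive astrocyte genes had 1 riser of 18, S1pr3, at 0.15 (SE 0.038, adjusted p = 0.0407; 0.0863 with the plate column as a factor), and 3 adjusted over the list alone (FDR 0.00193; adjusted p = 0.805 with an estimated correlation).

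Of 32 medium spiny neuron identity genes, all of them measured in these cortices, 1 rose and 3 fell, and 2 rose and 6 fell adjusted over the list alone (FDR 0.00876; adjusted p = 0.335 with an estimated correlation). Arpp21, a calmodulin regulator, fell by 0.11 (SE 0.020, adjusted p = 0.0014), with Arpp19 and Rgs4 at -0.07 and -0.08 (adjusted p = 0.019 and 0.0369; 0.0619 and 0.116 with the plate column as a factor). The list mean per mouse fell by 0.0348 (permutation p = 3e-04, 0.0087 adjusted over 29 lists). The shuffles ignored the library-name number, by which libraries deviated together. Oligodendrocyte and myelin genes moved apart: Enpp6 rose, while Qdpr, Tspan2 and Ugt8a fell by 0.13, 0.18 and 0.13, of 22 genes (FDR 0.0205; adjusted p = 0.821 with an estimated correlation), with 2 risen and 6 fallen adjusted over the list alone. Of 21 microglia markers, Ctss, cathepsin S, rose by 0.08 (SE 0.020, adjusted p = 0.0369; 0.05 and no longer called without the filter), and it was 1 adjusted over the list alone (FDR 0.0162; adjusted p = 0.821 with an estimated correlation).

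The 31 activity-regulated genes had a median of -0.06 and 0 calls over all genes or adjusted over the list alone (FDR 0.00357; adjusted p = 0.821 with an estimated correlation), with the immediate early gene Npas4 at -0.44 (SE 0.13, adjusted p = 0.116). The 16 meningeal fibroblast markers had a median of 0.12 and 0 calls by either count (FDR 0.00177; adjusted p = 0.821 with an estimated correlation). The other 22 lists had a camera FDR between 0.0616 and 0.941. They were the HD onset modifier and mismatch repair genes (FDR 0.612, 0 of 16 called), clustered protocadherins (0.401), interferon-stimulated genes (0.0616), nuclear OXPHOS genes (0.199), cholesterol biosynthesis genes (0.154), polycomb-repressed developmental regulators (0.452), heat shock genes (0.0829), p53 and DNA damage response genes (0.746), unfolded protein and integrated stress response genes (0.912), circadian clock genes (0.209), ribosomal protein genes (0.452), mitochondrially encoded genes (0.737) and glutamate and GABA receptor genes (0.199). The cell type and region lists among them were upper layer (0.0793) and deep layer (0.384) excitatory neurons, inhibitory interneurons (0.199), oligodendrocyte precursors (0.912), endothelial cells and pericytes (0.738), red blood cells (0.452), choroid plexus (0.647), thalamus (0.941) and hippocampus (0.214). Over the 12 contrasts, 72 of 348 list tests were called with the preset correlation and 0 with an estimated one.

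**Figure D2:**
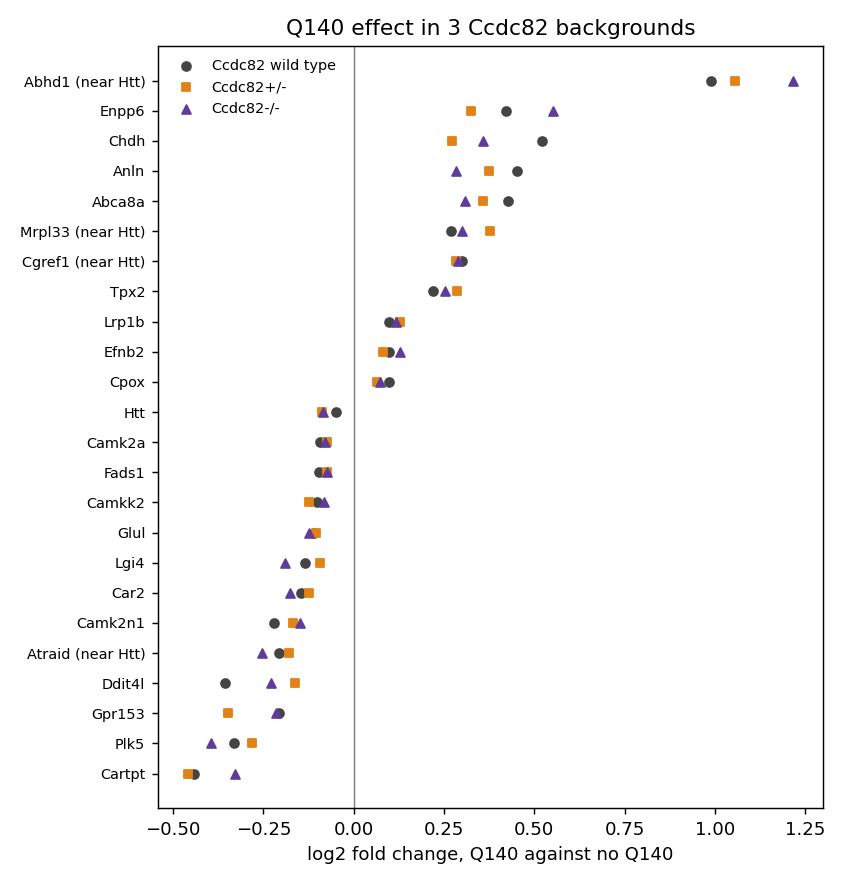
Log2 fold change of Q140 against no Q140 (horizontal axis) for named genes of the pooled Q140 effect (vertical axis), with 1 point for each of the 3 Ccdc82 genotypes and no error bars. Abca8a had values of 0.43, 0.36 and 0.31, and Cartpt of -0.44, -0.46 and -0.33.

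Of 145 tested genes within 5 Mb of Htt (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534), 11 were called in the pooled Q140 effect, 7.59% against 0.825% elsewhere. Gm2420 rose by 3.30, Abhd1 by 1.09 (SE 0.124, adjusted p = 2.73e-07), Mrpl33 by 0.32 (SE 0.025, adjusted p = 2.38e-13) and Cgref1 by 0.29 (SE 0.042, adjusted p = 2.15e-05), while Atraid fell by 0.21 (SE 0.035, adjusted p = 0.000294). Htt itself, counted among the 11, fell by 0.07 (SE 0.015, adjusted p = 0.0032) in the pooled effect. In Q140 against WT alone it was not called, with 232.8 ± 7.08 CPM (SD, n = 8) in WT and 224.9 ± 9.91 CPM (n = 8) in Q140, a log2 difference of -0.05 (SE 0.025, adjusted p = 0.725). Without the flanking genes, 59 genes rose and 98 fell.

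**Figure D3:**
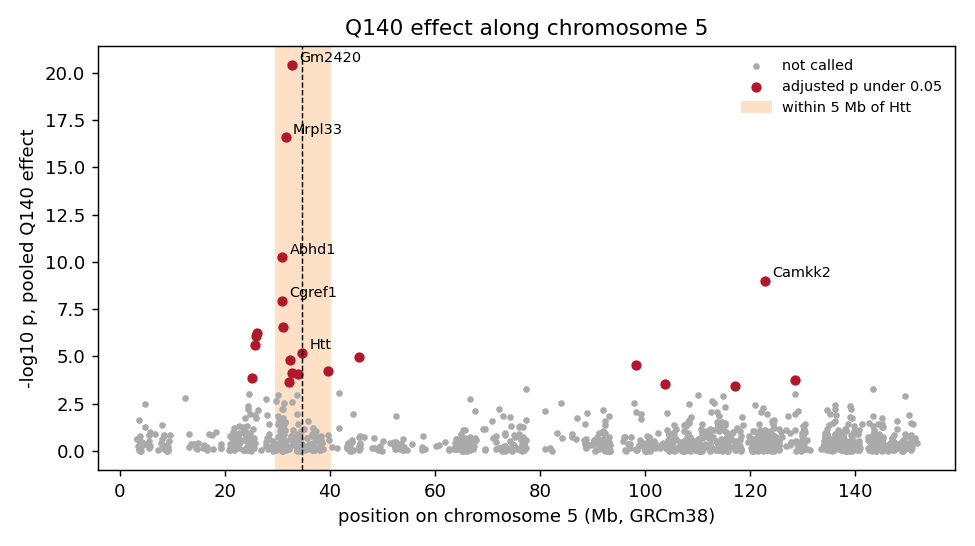
Unadjusted p of the pooled Q140 effect, as -log10 (vertical axis), for genes along chromosome 5 (horizontal axis, Mb, GRCm38). Of 145 genes within 5 Mb of Htt 11 were called, with 4 of 55 from 5 to 10 Mb away and 6 of 1126 farther away on the chromosome.

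The Q140 effect did not differ detectably between Ccdc82 genotypes. In edgeR 0 genes passed for the interaction with Ccdc82+/- or with Ccdc82-/-, with 674 and 567 genes at an unadjusted p under 0.05, and DESeq2 called 0 in each. Over all genes the median SE of the interaction was 0.0821 with Ccdc82+/- and 0.0836 with Ccdc82-/-. The called pooled Q140 effects had a median size of 0.12, so changes of that size could be missed. The simulation covered no interaction. Ccdc82 itself had an interaction of 0.11 (SE 0.077, adjusted p = 1) with Ccdc82+/- and Htt one of -0.04 (SE 0.036, adjusted p = 1). In the sex comparison of the pooled Q140 and pooled Ccdc82-/- effects, edgeR and DESeq2 called 0 genes in each, with 769 and 535 at an unadjusted p under 0.05 in edgeR.

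Whether genes kept their sign was examined in limma-trend fits of log2 CPM, with each background fitted alone and sex as a term. The 100 genes with the smallest p in such a fit of Q140 against WT were taken outside chromosomes 5 and 9. They kept their sign in 81% of cases on the Ccdc82+/- background and in 89% on the Ccdc82-/- background. In 99 permutations of the Q140 labels the share reached at most 80% on Ccdc82+/-, so that the one-sided permutation p was 0.01, the smallest that 99 permutations can give. On Ccdc82-/- it reached 92%, above the observed share in 1 permutation (permutation p 0.02). In the 4 other directions between backgrounds 79% to 85% kept their sign, with a permutation p of 0.01 to 0.04. Across 16797 genes, which are not independent replicates, Q140 effects of the edgeR fit in mice sharing no library correlated only weakly. The Pearson r was 0.0734 to 0.103 and the Spearman rho 0.106 to 0.147. Effects of Ccdc82 loss with and without Q140, where Ccdc82 alone was called, served for comparison. Their r was 0.0371 (rho 0.0954) for Ccdc82+/- and -0.0177 (rho 0.0351) for Ccdc82-/-. The lowest Q140 rho thus lay close to that for Ccdc82+/-, and the correlations were not tested.

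The Q140 signature score was higher on average in mice with the allele on each background, although single WT and Q140 mice overlapped. It averaged 0.134 ± 0.071 (SD, n = 8) in WT and 0.292 ± 0.0532 (n = 8) in Q140, a difference of 0.158 (exact permutation p = 0.000466), and the differences on Ccdc82+/- and Ccdc82-/- were 0.169 and 0.179 (exact permutation p 0.000155 each). Without genes on chromosomes 5 and 9, which hold Htt and Ccdc82, the 3 differences were smaller, at 0.111 (exact p = 0.00559), 0.0859 (exact p = 0.0159) and 0.109 (exact p = 0.000155). With 500 genes they were 0.0765 (exact p = 0.00622), 0.0558 (exact p = 0.0437) and 0.0660 (exact p = 0.00932). In Q140 with Ccdc82-/- it was 0.277 ± 0.0581 (n = 7), lower than in Q140 by a difference of -0.0148 (95% interval -0.0776 to 0.0475, exact p = 0.614). In Q140 with Ccdc82+/- it was 0.270 ± 0.0507 (n = 8), a difference of -0.0217 (95% interval -0.0774 to 0.0344, exact p = 0.412), which was -0.0440 (95% interval -0.0914 to 0.00317, exact p = 0.0656) without chromosomes 5 and 9 and -0.0329 (exact p = 0.0791) with 500 genes. Its sign was reversed with genes divided by their SD (0.0381) and with fallen genes alone (0.0110), so its direction was not settled, and with genes divided by their SD the difference with Ccdc82-/- was reversed as well (0.00274). The interaction terms were 0.0214 (permutation p = 0.625) with Ccdc82-/- and 0.0114 (permutation p = 0.798) with Ccdc82+/-. Both changed sign without chromosomes 5 and 9 (-0.00192 and -0.0253) and with 500 genes (-0.0105 and -0.0207), and that with Ccdc82-/- also with fallen genes alone (-0.0152). With the 50 genes, neither interval extended to a fall as large as the 0.158 by which Q140 exceeded WT, and in each fold 3 to 8 genes were called, so 50 were used. Without chromosomes 5 and 9 the interval reached -0.0914 with Ccdc82+/- and -0.0809 with Ccdc82-/-, beside 0.111. With 500 genes it reached -0.0697 with Ccdc82+/- and -0.0518 with Ccdc82-/-, beside 0.0765. A fall by most of the Q140 difference was thus not excluded for either genotype in those settings.

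**Figure D4:**
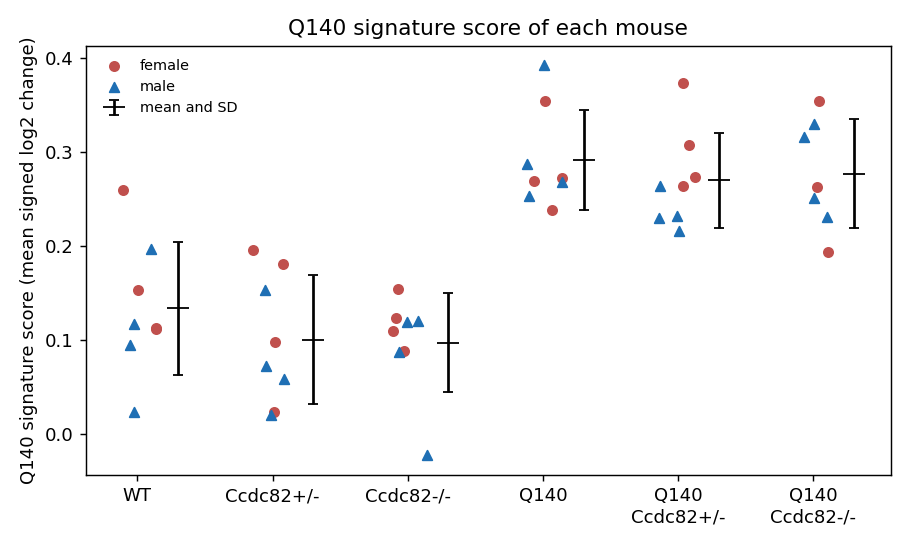
Q140 signature score per mouse (vertical axis, mean signed log2 difference from the WT mice kept in the fold) in the 6 genotypes, with points for mice and bars for the mean ± SD. The 3 groups with Q140 averaged 0.292, 0.270 and 0.277, and WT averaged 0.134.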

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

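The tests of a strain variant and of a response with no position effect near Htt, of a segment beyond 5 Mb, of differing amounts of meninges and of the meningeal list without mice that share a library-name number were chosen only after the result was seen.

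Called genes, Htt itself among them, clustered near Htt in the pooled Q140 effect (Fisher exact p 6.18e-08), which argues against a response with no position effect. Low counts are argued against as well, since the called genes near Htt had a median of 12.3 CPM. From 5 to 10 Mb away, 4 of 55 genes were called, 7.27% against 0.806% farther away or on other chromosomes (Fisher exact p 0.0011). A candidate explanation is a strain segment carried with the knock-in allele, which may reach beyond 5 Mb. An effect of the allele on its neighbours was not tested and stays open.

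Meningeal fibroblast markers were lower in Q140 with Ccdc82+/- than in Q140, which itself lay above WT (0.320, exact permutation p 0.0267, 0.695 adjusted). The median was -0.374 with median-of-ratios size factors, but these differed from the TMM factors by at most 0.00539 on the log2 scale, so normalization was not put to a test and stays open. The list mean per mouse differed with an exact permutation p of 0.00963, but this list was picked among many, and adjusted over 203 tests the p was 0.614, so a genotype difference stays open although the prediction named the unadjusted p. Differing amounts of meninges on single cortices cannot be told apart from it, as the genes correlated at 0.723 within genotypes. The exact p ignores that libraries sharing a name number deviated together: without males 1 and 2 of Q140 with Ccdc82+/-, which share 1, the difference of the list mean shrank from -0.413 to -0.233 (exact permutation p 0.044).

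Astrocyte markers were lower in the pooled Q140 effect. Relative to WT, the list mean was -0.0477 in Q140, but also -0.0526 in Ccdc82+/- and -0.0433 in Ccdc82-/- without Q140. In Q140 with Ccdc82+/- and with Ccdc82-/- it was -0.0901 and -0.103. A list mean below WT by the amount seen in Q140 was thus not particular to mice with the allele. An equal fall of all markers, as predicted for fewer astrocytes, is argued against, since 30% of the genes lay more than 2 standard errors from the list's median. Glul and Kcnj10 lay below it and Aqp4 and S100b above it, although Aqp4 (adjusted p = 0.523) and S100b (adjusted p = 0.465) were not called. Unequal falls of the markers from fewer astrocytes were not tested and stay open. The median of -0.059 with median-of-ratios size factors is no test of normalization either, which stays open. Differences between single brains stay open: the permutation p of the list mean was 0.00519, under the bound set in the prediction, but 0.0753 adjusted over 29 lists.

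Single libraries stood far from the others of their group in 10 of 102 groups of values tested, where chance gives about 5.1. The total was 61.37 M counts in Q140 with Ccdc82+/- male 2, with the nearest other at 51.11 M counts. The mitochondrially encoded share was 4.707% in WT male 3, with the nearest other at 4.56%. The Q140 signature score was -0.0223 in Ccdc82-/- male 4, with the nearest other at 0.0875. The astrocyte list mean was 0.1008 in Q140 female 1 and the reactive astrocyte list mean 0.509 in Q140 with Ccdc82-/- female 1. The red blood cell list mean was -3.377 in WT male 1, -3.973 in Q140 female 3 and -3.174 in Q140 with Ccdc82+/- female 2. The interferon list mean was 0.255 in Ccdc82+/- female 1 and 0.5305 in Q140 with Ccdc82-/- female 1.

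List medians of the interaction of Q140 with Ccdc82+/- passed with the preset correlation for activity-regulated genes (0.263; adjusted p = 0.938 with an estimated correlation), reactive astrocyte genes (-0.135; adjusted p = 0.938), meningeal fibroblast markers (-0.436; adjusted p = 0.587) and ribosomal protein genes (0.055; adjusted p = 0.421). With Ccdc82-/- they passed for deep layer markers (-0.071) and oligodendrocyte and myelin genes (-0.11), each with an adjusted p of 0.878 with an estimated correlation.

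The counts of called genes were set against 100 splits with shuffled labels, the real one included. For the pooled Q140 effect 1 split reached 168 genes and the highest other called 5. For Q140 against WT 1 split reached 6 and the highest other called 1. For Q140 on Ccdc82+/- the split count was also 1 (6 genes, highest other 1). These counts argue against chance, although 1 of 100 is the smallest share that these splits can give. For Q140 on Ccdc82-/- the split count was 2 (4 genes, highest other 6). A shuffled split thus called more genes than the real labels, so chance is not excluded for that comparison. Where Ccdc82 was the 1 gene called, as many were called in 3 splits for the pooled Ccdc82-/- effect (highest other 1), 2 for Q140 with Ccdc82+/- against Q140 (highest other 1), 7 for Ccdc82+/- against WT (highest other 1), 7 for Ccdc82-/- against WT (highest other 9), 6 for Q140 with Ccdc82-/- against Q140 (highest other 99) and 5 for the pooled Ccdc82+/- effect (highest other 1). A split with any 1 call reaches a count of 1, so these counts do not test the fall of Ccdc82 itself. In Ccdc82-/- against WT it fell by 1.61 (SE 0.058, adjusted p = 3.01e-27), at 4.64 to 6.30 CPM against 14.3 to 19.1 CPM. The interactions and sex differences called 0 genes, so all 100 splits reached them. The highest other was 2 for Ccdc82+/-, 1277 for Ccdc82-/-, 1 for the sex difference of Q140 and 88 for that of Ccdc82-/-. The splits with 99, 1277 and 88 genes may reflect a structure of the samples, which was not tested.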

How the results depend on the processing

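The library-name block, and the score from genes chosen on the Ccdc82+/- background, were tests chosen only after the result was seen. With 50 genes so chosen, the score of Q140 with Ccdc82-/- differed from that of Q140 by -0.0311 (exact permutation p 0.301). With 500 such genes outside chromosomes 5 and 9 the difference was -0.00920 (exact permutation p 0.598). The counts of 1 gene for the loss of Ccdc82 and of 0 for the interactions held under every alternative run. Q140 against WT held 24 genes with DESeq2 and 23 with 2 surrogate variables. Q140 on Ccdc82+/- held 2 with the plate column as a factor, 11 with surrogate variables and 3 with the compared groups alone, and Q140 on Ccdc82-/- held 2 with the replicate block against 4 without. The pooled Q140 effect ranged from 140 to 297 genes, the latter with surrogate variables; with limma-trend on FPKM 90 rose and 81 fell, against 65 and 103, and the causes were not tested. The list tests called 0 of 348 with an estimated correlation. Of 55 named calls, 46 were kept with the plate column, 51 with the replicate block and 55 with DESeq2, fits of the compared groups alone kept 10 of 17, and 0 reversed. Ddit4l, Camk2n1, Abca8a, Mrpl33, Abhd1, Camkk2, Gpr153 and Car2 lost their call in some setting of a single comparison, and Arpp19, Ctss, Kcnj10, Rgs4 and S1pr3 in some setting of the pooled effect. Among the score differences by Ccdc82 genotype within Q140 mice, the lowest exact permutation p was 0.0656, for a difference of -0.0440 without chromosomes 5 and 9. The difference of Q140 with Ccdc82+/- changed sign to 0.0381 with genes divided by their SD and to 0.0110 with fallen genes alone, and that with Ccdc82-/- to 0.00274 with genes divided by their SD.

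The replicate block assumed that numbers pair mice across genotypes. Over 115 pairs with 1 number the mean correlation of deviations was 0.0192, against -0.00543 over 345 other same-sex pairs of different genotype. Of 47 libraries, 13 correlated best with their own number. No clear pairing by the numbers was seen, and it was not put to a test. With that block Abhd1 lost its call on Ccdc82+/- (adjusted p = 0.0876) and on Ccdc82-/- (0.0508), as did Car2 on Ccdc82-/- (0.0829) and Ctss in the pooled effect (0.0559).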

Other observations

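The test of the library-name number was chosen only after the result was seen.

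Libraries that shared the first number of their name, which the labels do not explain, deviated together. Over 38 same-sex pairs of different genotype the mean correlation of deviations was 0.0848, against -0.00683 over 422 other pairs (one-sided permutation p 0.0015). By the labels, mice that shared a number were always of the same sex. A shared litter, cage or day of dissection may be the source, and the labels do not tell which. With that number as a random block the consensus correlation was 0.142. The permutation tests of list means, scores and kept signs, and the splits, moved single mice, so their results ignore this sharing.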
